A study of Mus musculus with 5 samples.

How the data were processed

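Gene expression was measured on Affymetrix MG-U74Av2 arrays, 1 array per sample, in CD8 T cells of OT-I mice stimulated with antigen and B7-1 in the presence of human IL-2. The groups came from the sample titles: 48 h without IL-21 (2 arrays), 48 h with IL-21 (2 arrays) and 72 h with IL-21 (1 array). The titles call each sample a biological replicate and do not say whether cultures or mice were separate, so p-values measure the spread between these samples. A 72 h sample without IL-21 was not analysed here, so IL-21 and time could not be separated at 72 h.

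The deposited values are probe set intensities on a linear scale, summarised with MAS5 per the submitters' processing notes. The software version, the scaling target and the detection calls are not given in the sources used here. The columns have different trimmed means, so the deposited intensity values had not been brought to a common target. Every probe set thus carries the overall signal of its array, whose source is not known, as well as its transcript's level. MAS5 signals are also noisy near background. All per-sample columns were matched to samples by name.

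Gene names came from a probe table with platform annotation, updated through Entrez gene identifiers to the symbols of the GRCm38.p6 gene table, with 10817 of 10833 singly named probe sets matched. Of the 12422 probe sets that were not controls, 10833 had 1 gene name, 396 had several and were given none, and 1193 were unnamed. The named ones stood for 8251 genes.

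An offset of 1.53 signal units, the 10th percentile of all values, was added before taking log2, so differences of dim probe sets are understated. The design written before the data were examined assumed that the deposited scaling between arrays could be kept. Since the values proved not to be scaled, quantile normalisation was used instead, before any test was run, and the deposited scaling became an alternative. Quantile normalisation removes any shift that all genes share, so directions are relative to the bulk of probe sets. Probe sets whose mean log2 value over the 5 arrays exceeded the 40th percentile were kept, which removed 4969 and left 7453, of which 6708 had 1 name. Group levels are 2 raised to the mean normalised log2 value and include the offset.

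Differences were tested with limma 3.58.1 in R 4.3.3, with group means for the 3 groups fitted to all 5 arrays (2 residual degrees of freedom), empirical Bayes variances with a trend on mean signal, two-sided tests and Benjamini-Hochberg adjustment over the 7453 probe sets at 0.05. The contrasts were IL-21 against none at 48 h and 72 h against 48 h with IL-21. The lone 72 h array adds nothing to the variance estimate. At 48 h, probe sets at least 2-fold apart without overlap were also counted. The 23 gene lists were fixed before the data were examined, and 22 had at least 5 measured members. Each gene was represented by its probe set with the highest mean. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance and not whether they differ from other genes, were alternatives. No list call in either comparison held with an estimated correlation. This included lists whose estimated correlation lay below 0.01, so a call lost in that test is by itself no sign of correlated genes. With an estimated correlation camera rests on the 2 residual degrees of freedom. Even the MYC and ribosome biogenesis list at 72 h, with a camera p of 6.2e-21 at the preset correlation, then had an unadjusted p of 0.032. List medians were also placed among 10000 random lists of the same size matched on mean signal.

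Named genes followed a rule fixed before the data were examined. At 48 h it took the 10 genes per direction with the largest differences among those that passed, filled up by the smallest p where fewer passed, and at 72 h it took 8 per direction. It also took up to 4 members of each list at 48 h and 2 at 72 h by smallest p, and 12 genes always, of which 1 is not reported here. Genes outside the rule are said to be chosen after their values were seen.

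The procedure was tested on simulated data before use. In 20 simulations of 7453 probe sets 200 were changed, divided evenly between the 2 comparisons. The 48 h comparison called 5.04% of its changes of 2-fold, 41.9% of 4-fold and 64.2% of 8-fold, and 0.0258% of unchanged probe sets. For the 72 h comparison the shares were 1.55%, 21.6% and 53.9%, and 0.0177% of unchanged probe sets. In the arrays themselves 832 probe sets passed at 72 h, more than were changed in a simulation, so these shares do not give the power of that comparison. A list shifted by 0.25 on the log2 scale was called in 10 of 10 simulations of either comparison, in which genes varied independently.

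Alternatives fixed in advance were the offset, the scaling between arrays, the filter, the variance trend, gene means, the replicate number as a block, other list tests and leaving out each 48 h array. Scaling to a common trimmed mean, scaling on the labelled control transcripts and a baseline of all 4 arrays at 48 h were chosen after seeing the data. Scaling on the control transcripts used each array's median over their 9 probe sets. Figures were drawn with matplotlib 3.10.9.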

Results

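RNA was profiled from CD8 T cells of OT-I mice, a C57BL/6 line whose T cells carry a transgenic receptor for a peptide of ovalbumin. CD44-low cells were stimulated in culture on microspheres that carried the peptide bound to its MHC molecule together with B7-1, the ligand of the costimulatory receptor CD28. Human IL-2 was in all cultures, and IL-21, a cytokine that signals through STAT3, was added to some. Total RNA was converted to biotin-labelled cRNA and hybridised to a mouse oligonucleotide array with 12488 probe sets. There were 2 arrays at 48 h without IL-21, 2 at 48 h with IL-21 and 1 at 72 h with IL-21, each labelled as a biological replicate. Of the 12422 probe sets that were not controls, 7453 passed the filter on low signal, and these stood for 5610 named genes. With 5 arrays, the number of arrays limited the precision.

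Before any scaling the arrays differed in overall signal. The trimmed mean signal was 105 on both 48 h arrays with IL-21, 75.3 and 65.2 on the 48 h arrays without it, and 65.8 on the 72 h array. The unscaled signals were 1.48-fold higher with IL-21 at 48 h by the median over the 7453 probe sets, and 96.0% of them were higher. Bacterial and phage transcripts that served as labelled hybridisation controls (9 probe sets) were 1.62-fold higher by their median. All comparisons therefore used quantile-normalised values, under which the median log2 difference between the groups was -0.01 in both comparisons. Signal ratios between the 3' and 5' probe sets lay between 0.886 and 1.03 for beta-actin and between 0.796 and 0.877 for Gapdh, and between 2.40 and 3.99 for the transferrin receptor.

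**Figure D1:**
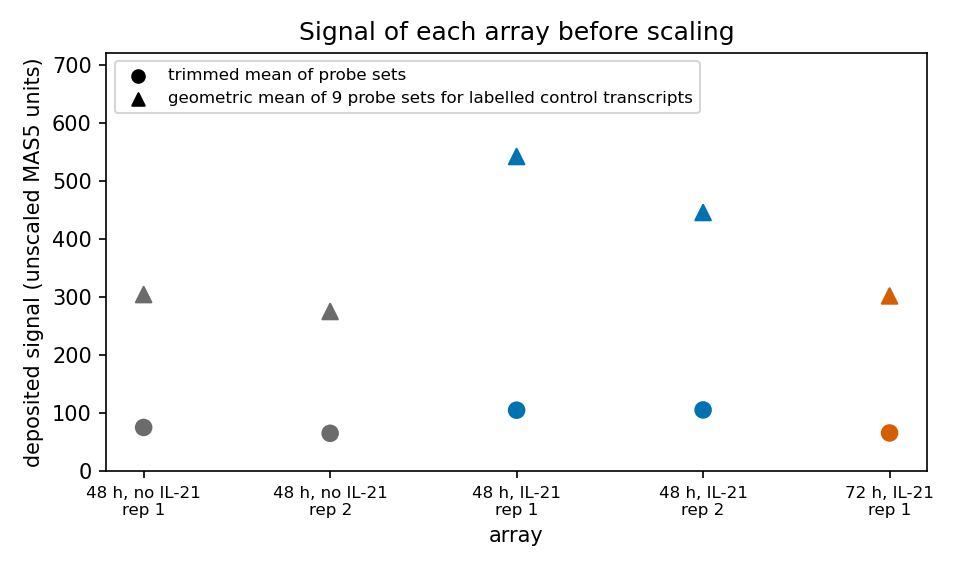
Deposited signal of each array in unscaled MAS5 units, as the trimmed mean over probe sets (circles) and the geometric mean of 9 labelled control probe sets (triangles), with the arrays along the horizontal axis coloured by group. Both measures were highest on the 2 arrays with IL-21 at 48 h, with trimmed means of 105 against 65.2 to 75.3 on the other arrays.

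The first comparison asked what IL-21 added at 48 h to stimulation through antigen and B7-1. In the fit without replicate numbers no gene passed the test at this number of arrays, so the values below describe 2 arrays against 2. Cd8a, the alpha chain of the CD8 coreceptor, had a normalised signal of 721 with IL-21 and 408 without it (log2 difference 0.82, SE 0.12), and Cd8b1, the beta chain, 1003 and 688 (0.54, SE 0.23). Gzmb, which encodes the cytotoxic protease granzyme B, had 3630 with IL-21 and 2082 without (0.80, SE 0.50). Its single arrays overlapped between the groups, and the difference lay between 0.17 and 1.44 when each array was left out in turn, as that of Cd8b1 did between 0.19 and 0.90. Sod1, the cytosolic superoxide dismutase, had 267 with IL-21 and 495 without (-0.89, SE 0.15), and Cdkn1a, the cell cycle inhibitor p21, 138 and 247 (-0.84, SE 0.19). Of the 7453 probe sets, 0 had an adjusted p under 0.05 in limma, and the smallest was 0.465. An unadjusted p under 0.05 was reached by 327 probe sets, 190 higher and 137 lower with IL-21, where chance alone gives 373. In the unscaled values 696 probe sets passed, all higher with IL-21, and after scaling on the control transcripts 38 did, 3 higher and 35 lower. With the replicate number as a block 11 passed, 9 higher and 2 lower, among them Gzmb, Cd8a and Sod1. An unadjusted p under 0.05 was reached by 812 probe sets in that limma fit, above the 373 of chance. The SE of Gzmb was 0.08 in that fit, but no label ties the replicate numbers to a day, batch or mouse.

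By size alone, 103 probe sets differed at least 2-fold without overlap between the 2 groups, 63 higher and 40 lower with IL-21. Chance leaves 33.3% of probe sets without overlap at any size, and 33.8% were seen. The named genes with the smallest p on the higher side, besides Cd8a, were Sf3b1, a spliceosome component (1.13), Prp2 (2.48), Tmem129 (1.70), Wnk1, a kinase (1.58), Ddx6, an RNA helicase (1.26), Cbx5, a heterochromatin protein (1.14), Otud4 (1.03), Smarcc1, a chromatin remodeller subunit (0.88) and Atp6v0e2 (1.02). On the lower side, besides Sod1 and Cdkn1a, they were Dlgap4 (-1.58), Krt6a (-1.91), the copper transporter Atp7b (-1.67), the ribosomal protein gene Rps19 (-0.67), Etf1, a translation termination factor (-0.59), Gas5 (-0.44), Aifm1 (-0.59) and Ltb, which encodes lymphotoxin beta (-0.69). None of these passed the threshold, with adjusted p between 0.585 and 0.967 in limma. The other probe set of Sf3b1, Tmem129, Otud4, Krt6a and Gas5 had the opposite sign. Of the others of Wnk1, 1 had the same sign (1.40) and 1 the opposite (-0.12), and of those of Etf1, 1 had the same sign (-0.13) and 2 the opposite (0.09 and 0.32). All 3 probe sets of Ddx6 were higher with IL-21.

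Of 14 measured genes known to respond to IL-21 and STAT3, 6 were higher and 8 lower at 48 h, with a median log2 difference of -0.00, and the list did not pass. The median lay between -0.36 and 0.23 when each array was left out in turn, and it differed by 0.60 between the 2 IL-21-free arrays. Among them Pim1, a kinase gene under STAT control, differed by 0.26 (SE 0.13), the transcription factor gene Batf by 0.54 (SE 0.36), Nfil3 by -0.62 (SE 0.49) and Stat3 itself by -0.19 (SE 0.20). Socs3, the feedback inhibitor of STAT3 signalling, differed by -0.34 (SE 0.62), and Il2ra, the IL-2 receptor alpha chain, by -0.62 (SE 0.33). Of the 9 cytotoxic molecules measured, 6 were higher and 3 lower, with a median of 0.03, which lay between -0.13 and 0.56 when each array was left out. Beside Gzmb these included Srgn, the granule proteoglycan (0.31), Crtam (0.30), the granzyme inhibitor Serpinb9 (-0.28) and Prf1, which encodes perforin (0.03, SE 0.70). Ifng, Eomes, Prdm1, Bcl6 and Il10 lay below the filter on low signal, and Tbx21 and Il21r were not named in the probe annotation used here. No member of these lists passed the limma threshold over all probe sets or adjusted over the list alone.

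Cell cycle genes were shifted upward and glycolysis genes downward with IL-21 at 48 h when each list was set against all other genes. Of 60 cell cycle genes, 40 were higher and 20 lower, with a median log2 difference of 0.08, which lay between 0.02 and 0.09 when each array was left out. Examples were Aurka, a mitotic kinase (0.86, SE 0.17), Prim1, a DNA primase subunit (0.77), Gmnn, a regulator of replication licensing (0.46), and Ube2c, which acts in mitotic exit (1.00). Of 28 genes of glycolysis and the hypoxia response, 19 were lower and 9 higher, with a median of -0.14, between -0.27 and -0.09 when each array was left out. Examples were the hypoxia-responsive Ndrg1 (-0.53, SE 0.19), Pdk1, an inhibitory kinase of pyruvate dehydrogenase (-0.40), Bnip3 (-0.56) and the glycolytic enzyme Tpi1 (-0.20). No member passed the limma threshold, over all probe sets or adjusted over the list alone. Both lists had an adjusted p of 0.0254 in camera with its preset correlation, an adjusted p of 0.894 with an estimated correlation and an adjusted p of 0.941 in fry. Without the first IL-21-free array both calls held, with adjusted p of 0.00769 and 0.00418. Leaving out the second IL-21-free array gave adjusted p of 0.222 and 0.198, and leaving out either IL-21 array gave 0.0734 or 0.0716. Relative to the median of all probe sets, both lists kept their side under all 5 scalings, but in the unscaled values the glycolysis median was 0.42 and after scaling on the control transcripts the cell cycle median was -0.33.

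The other 20 lists tested did not pass at 48 h in camera, with adjusted p between 0.499 and 0.931, and none of the members named here passed in limma over all probe sets. Among 39 genes of the MYC and ribosome biogenesis list 19 were higher and 20 lower (median -0.01), including the nucleolar helicase Ddx21 (0.78), the chaperonin subunit Cct2 (0.89), Ranbp1 (0.52) and Gnl3 (0.38). Effector cytokines and chemokines had a median of -0.17, with Il3 (-0.82), Lta (-0.71, another probe set 0.30) and Csf1 (0.33) beside Ltb. Effector and memory transcription factors had a median of 0.04, with Id2 (0.62), Rora (-1.01), Foxp1 (0.31) and Zeb1 (-0.38), and naive and memory T cell genes 0.05, with Ccr7 (-0.41), Bcl2 (-0.26), Cxcr4 (-0.55) and Btg1 (-0.31). Activation and costimulation receptors had a median of -0.10, with Tnfrsf18 (-0.38), Tnfrsf4 (-0.36), Klrk1 (0.44) and Tfrc (0.27, another probe set -0.35). Inhibitory receptors had 0.09, with Ctla4 (-0.38), Lag3 (-0.32), Cd160 (0.29) and Klrd1 (0.85), and homing receptors and integrins -0.07, with Itgb1 (0.74, another probe set -0.04), Cd9 (0.44) and Ccr6 (-1.19). In the T cell receptor and CD8 list the median was -0.01, Cd3e and Cd3g differed by -0.25 and -0.18, and 1 gene, Cd8a, passed when p was adjusted over the list alone.

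Signalling and metabolic lists did not pass either. Cytokine receptor and JAK-STAT genes had a median of -0.11, at the 1.58th percentile of matched random lists, with Ifnar2 (0.58), Ifngr1 (-0.49) and Stat6 (-0.30). Interferon-stimulated genes had 0.03, with Gbp2 (0.33), Irgm1 (0.62), Gbp3 (0.61) and Ly6e (0.19). Apoptosis and survival genes had -0.08, with Bad (0.74, another probe set -0.26) and Tnfaip3 (-0.58) beside Cdkn1a and Bnip3. Oxidative phosphorylation and citrate cycle genes had -0.04, with Ndufs3 (-0.39), Cyc1 (0.18), Uqcrc2 (0.24) and Ndufc1 (0.21). Cholesterol and fatty acid synthesis genes had -0.05, with Scd2 (-0.54, another probe set 0.16), Ebp (-0.49), Fasn (0.49) and Fdft1 (0.37). Unfolded protein and stress genes had -0.09, with the chaperone gene Hspa5 (0.42), Ddit3 (-0.59), Trib3 (-0.81) and Manf (-0.30). Without the first IL-21-free array the median was 0.33 for interferon-stimulated genes and -0.27 for cytokine receptor genes. Without the first IL-21 array it was -0.43 for effector cytokines. With 1 array left out, IL-21 is not balanced against the replicate numbers, so such fits mix the 2. The interferon median differed between the second and the first replicate by -0.52 without IL-21 and by -0.25 with it. Between IL-21 and none it differed by -0.08 and 0.16 within the same number. Medians of lists that did not pass moved when each array was left out in turn, between -0.25 and 0.33 for interferon-stimulated genes, -0.43 and 0.22 for effector cytokines, -0.29 and 0.17 for naive and memory genes, -0.29 and 0.05 for homing receptors, and -0.22 and 0.06 for inhibitory receptors. Of the 22 lists, 17 had medians of either sign across these fits, and so had 13 of the 103 genes chosen by the fixed rule, among them Klrd1 (-0.37 to 2.08). Median, mean and camera direction differed in sign in 7 of the lists at 48 h, none of them past the threshold.

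Markers of other cell types gave no list call at 48 h either. Medians were -0.02 for 9 B cell markers, with Cd37 (-0.43), Cd79b (0.98), Pax5 (0.23) and Ighm (0.22), and 0.12 for 18 myeloid and dendritic cell markers, with H2-Eb1 (-1.07), Xcr1 (0.80), Ccl22 (0.34) and H2-Ab1 (-0.24). They were -0.36 for 5 CD4 and regulatory T cell markers, including Nrp1 (-0.39) and Cd4 (-0.21), and -0.27 for 6 erythroid, platelet and stromal markers, with Pecam1 (-1.18), Epor (-0.52), Col1a1 (-0.48) and Col1a2 (0.07). Leaving out each array in turn gave -0.12 to 0.38 for the B cell, -0.10 to 0.22 for the myeloid, -0.56 to -0.07 for the CD4 and -0.69 to 0.22 for the stromal median. Of the NK cell list 12 genes were on the array and 0 passed the filter.

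**Figure D2:**
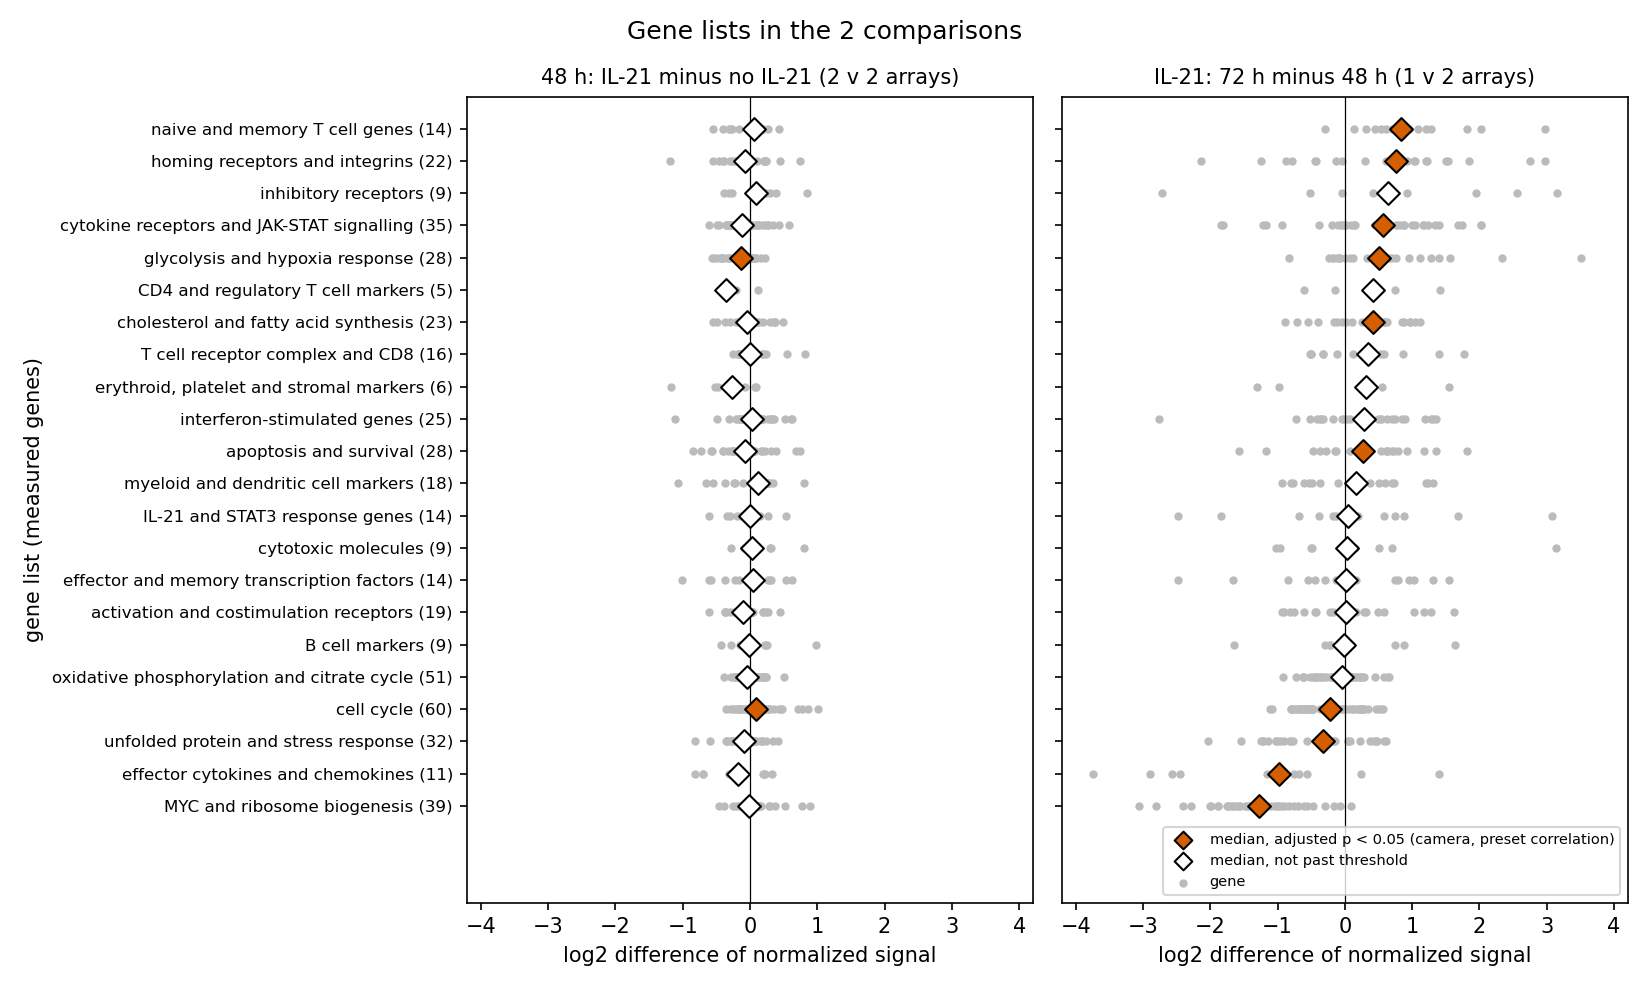
Log2 difference of normalised signal (horizontal axes) for the genes of the 22 tested lists (vertical axis, with the number of measured genes), for IL-21 against none at 48 h on the left and 72 h against 48 h with IL-21 on the right. Grey points are genes, diamonds are list medians, and filled diamonds passed camera with its preset correlation. The MYC and ribosome biogenesis list lies lowest at 72 h (median -1.27) and near 0 at 48 h (median -0.01). Among the filled medians, the 48 h glycolysis median and 4 above 0 at 72 h change sign in the unscaled values, and the 48 h cell cycle median does after scaling on the control transcripts. Open medians change sign as well, such as that of the T cell receptor and CD8 list at 72 h (0.34 to -0.36 in the unscaled values).

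The second comparison asked how the cells stimulated with IL-21 differed between 48 and 72 h. It set 1 array against 2, so the 72 h values have no replicate check of their own, and the test assumed that the lone array varies like the 48 h groups. In limma, 832 of 7453 probe sets passed at an adjusted p under 0.05, 301 higher and 531 lower at 72 h, for 258 and 455 genes. At least 4-fold were 105 of them, 44 higher and 61 lower. The share called higher, 36.2%, depended on the scaling. It was 18.1% (122 higher, 552 lower) with arrays centred on their medians, 4.75% (101 and 2027) in the unscaled values and 72.3% (655 and 251) after scaling on the control transcripts. The median of all probe sets moved by -0.17, -0.58 and 0.30 in these scalings.

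By log2 difference, the genes called higher at 72 h were led by Gsn, the actin-severing protein gelsolin (30.2 to 704, log2 difference 4.54, SE 0.78), Selenbp1 (5.55 to 126, 4.51, SE 0.69) and Cd7, a T cell surface protein (23.0 to 516, 4.49, SE 0.37). Cyp2s1, a cytochrome P450 (4.04), Prr5, a subunit of mTOR complex 2 (3.94), and Mxd4, a MAX-binding antagonist of MYC (3.85), rose from signals of 8.61, 8.53 and 13.6. Aldoc, a glycolytic aldolase (3.51), and S100a4, a calcium-binding protein (3.48), rose as well. The genes called lower were led by Lta, which encodes lymphotoxin alpha (149 to 11.2, -3.74, SE 0.51), Hnrnpab, an RNA-binding protein (-3.11), and Srm, spermidine synthase (733 to 87.7, -3.06, SE 0.18). Pdia6, a disulphide isomerase of the endoplasmic reticulum (-3.02), Ccl3, an inflammatory chemokine (-2.90), Taf1d, a subunit of an RNA polymerase I initiation factor (-2.84), Celf1, an RNA-binding protein (-2.82), and Gnl3, the nucleolar protein nucleostemin (-2.81), followed. These 16 genes had adjusted p between 0.00928 and 0.0242 in limma. The Hnrnpab, Pdia6 and Celf1 probe sets ended at signals of 3.46, 2.80 and 6.76. These signals, the 11.2 at which Lta ended, and those from which Selenbp1, Cyp2s1, Prr5, Mxd4 and S100a4 started, the highest of them 16.1, are low, and detection was not tested, so the size and rank of these differences are uncertain. The same holds for Cxcr4 and Ccr4 below. Another probe set gave -1.21 for Hnrnpab, all 3 probe sets of Pdia6 were lower, and for Lta and Celf1 they had the opposite sign (0.07 and 0.06).

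**Figure D3:**
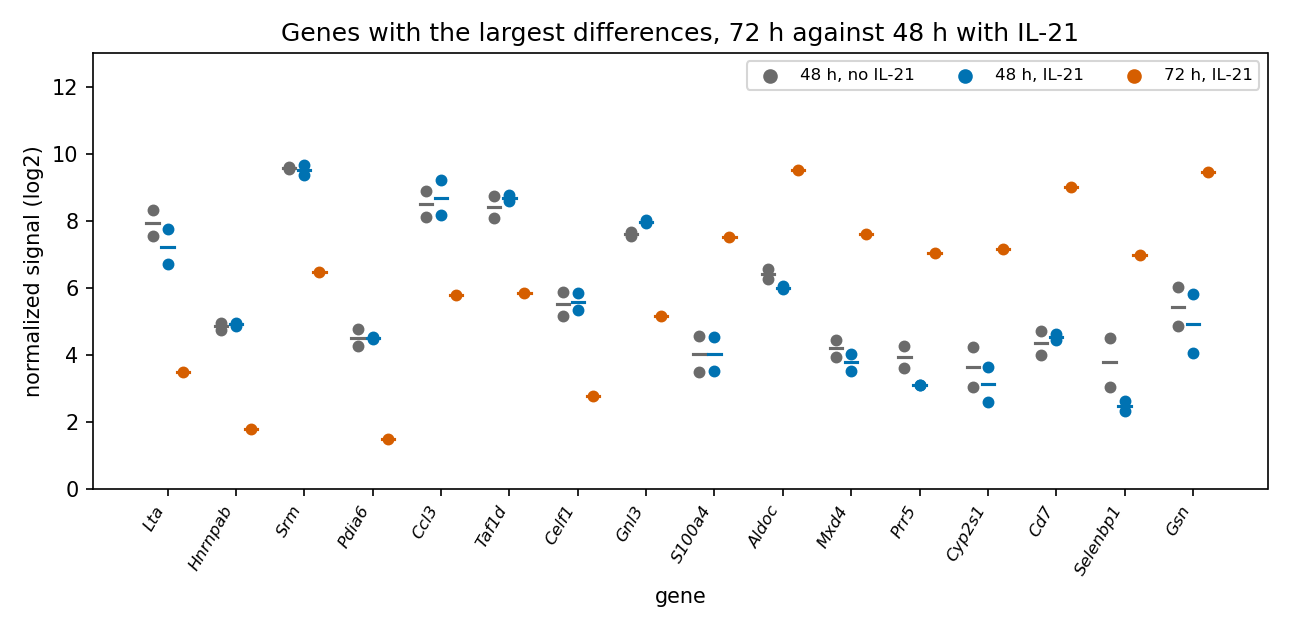
Normalised signal (log2, vertical axis) of the 16 genes with the largest differences between 72 and 48 h with IL-21 (horizontal axis), with a point per array and short lines at group means. Grey points are 48 h without IL-21, blue 48 h with IL-21 and orange the single 72 h array, which lies beyond all 4 arrays at 48 h for each gene. For Lta and Celf1 a further probe set, not drawn, moved by 0.07 and 0.06.

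The list of MYC and ribosome biogenesis genes was shifted downward on the single 72 h array. Of 39 measured, 30 were called lower and 0 higher in limma, 33 when adjusted over the list alone, and 38 of 39 had a negative difference. The median log2 difference was -1.27. Srm fell 8.36-fold and Gnl3 from 251 to 35.8. Myc itself, chosen after its value was seen, fell by 1.17 on the log2 scale (SE 0.23). The list had an adjusted p of 1.4e-19 in camera with its preset correlation and an adjusted p of 0.432 with an estimated correlation, and fry gave an adjusted p of 0.0344. The list median was lower on the 72 h array than on each of the 4 arrays at 48 h, by values between -1.36 and -1.23, while medians between 48 h arrays lay between -0.09 and 0.02.

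The list of unfolded protein and stress response genes was shifted downward relative to other genes, with 8 of 32 called lower (9 when adjusted over the list alone), 0 called higher and 24 not called. By sign 22 were lower and 10 higher, with a median of -0.32 (camera adjusted p = 0.00795, adjusted p = 0.432 with an estimated correlation). Hsph1, a cytosolic chaperone, fell from 366 to 89.4 (-2.04, SE 0.18), and Slc7a5, a subunit of the large neutral amino acid transporter, from 1045 to 360 (-1.54, SE 0.16). Of 60 cell cycle genes 4 were called lower (1 when adjusted over the list alone) and 0 higher, and by sign 41 were lower and 19 higher, with a median of -0.23 (camera adjusted p = 0.0308, adjusted p = 0.524 with an estimated correlation). Those called were the replicative helicase genes Mcm2 (-1.12) and Mcm5 (-0.81) and, chosen after their values were seen, Mcm3 (-0.72) and the phosphatase gene Cdc25a (-1.08). The cell cycle call ended after scaling on the control transcripts, where the median was -0.01, with a stricter filter, and against all 4 arrays at 48 h.

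The list of effector cytokines and chemokines was shifted downward, with 4 of 11 called lower, 1 higher (the same counts when adjusted over the list alone) and 6 not called. By sign 9 were lower and 2 higher, with a median of -0.98 (camera adjusted p = 0.0308, adjusted p = 0.539 with an estimated correlation). Beside Lta and Ccl3, Tnf (-2.56) and Ccl4 (-2.45), chosen after their values were seen, were called lower, and Ltb rose from 702 to 1858 (1.40, SE 0.20). The call ended without the first IL-21 array at 48 h (median -0.74, adjusted p = 0.0807), in the unscaled values, and under both other filters on low signal.

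The list of glycolysis and hypoxia response genes was shifted upward relative to other genes, with 7 of 28 called higher (9 when adjusted over the list alone), 0 called lower and 21 not called. By sign 21 were higher and 7 lower, with a median of 0.51 (camera adjusted p = 3.9e-04, adjusted p = 0.432 with an estimated correlation). Aldoc rose from 64.0 to 727, and Ndrg1 from 150 to 758 (2.34, SE 0.23). In the unscaled values the list median was -0.10, above the -0.58 of all probe sets. Of 51 oxidative phosphorylation and citrate cycle genes, Cyc1 (-0.92) and Uqcrq (-0.63), both parts of respiratory complex III, were called lower and 0 higher (1 lower when adjusted over the list alone). Their list median was -0.05 (camera adjusted p = 0.442, adjusted p = 0.538 with an estimated correlation), and fry called the list lower (adjusted p = 0.0349). Another probe set of Cyc1 had the opposite sign (0.16).

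The list of naive and memory T cell genes was shifted upward, with 4 of 14 called higher (8 when adjusted over the list alone), 0 called lower and 10 not called. By sign 13 were higher and 1 lower, with a median of 0.83 (camera adjusted p = 3.9e-04, adjusted p = 0.432 with an estimated correlation). Those called were the chemokine receptor genes Cxcr4 (11.6 to 91.5, 2.98, SE 0.45) and Ccr7 (204 to 470, 1.20, SE 0.19) and, chosen after their values were seen, the antiproliferative gene Btg2 (1.09) and the transcription factor gene Lef1 (0.96). The homing receptor and integrin list was also shifted upward, with 7 of 22 called higher, 1 lower (9 and 3 when adjusted over the list alone) and 14 not called. By sign 14 were higher and 8 lower, with a median of 0.76 (camera adjusted p = 0.0144, adjusted p = 0.432 with an estimated correlation). Cd47, the surface ligand of SIRP-alpha, rose from 191 to 556 (1.54, SE 0.21), and Ccr4, a chemokine receptor, fell to 7.71 (-2.15, SE 0.33).

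The list of cytokine receptor and JAK-STAT genes was shifted upward, with 5 of 35 called higher, 2 lower (10 and 3 when adjusted over the list alone) and 28 not called. By sign 25 were higher and 10 lower, with a median of 0.56 (camera adjusted p = 0.0137, adjusted p = 0.506 with an estimated correlation). Ifngr1, an interferon gamma receptor chain, rose by 1.74 (SE 0.27), while Socs2 and Cish, inhibitors of cytokine signalling, fell (-1.81 and -1.84). Without the first IL-21 array at 48 h the list had an adjusted p of 0.0516. Of 23 cholesterol and fatty acid synthesis genes, 5 were called higher, 0 lower (8 and 1 when adjusted over the list alone) and 18 not called. By sign 16 were higher and 7 lower, with a median of 0.41 (camera adjusted p = 0.0144, adjusted p = 0.432 with an estimated correlation). Those called were the desaturase gene Scd1 (1.11) and Nsdhl, a sterol synthesis enzyme (0.97), and, chosen after their values were seen, Msmo1 (0.96), Mvd (0.88) and Fdps (0.59). Of 28 apoptosis and survival genes, 3 were called higher, 0 lower (5 and 1 when adjusted over the list alone) and 25 not called. By sign 21 were higher and 7 lower, with a median of 0.27 (camera adjusted p = 0.0308, adjusted p = 0.432 with an estimated correlation). Those called were Tnfaip3, the NF-kappaB inhibitor A20 (1.81), Bcl2l11, the death-promoting BIM (1.18), and, chosen after its value was seen, Traf1 (1.36). The cholesterol call ended in the unscaled values, where the median was -0.27, with arrays centred on their medians and after scaling on the control transcripts. The apoptosis call ended without the second IL-21 array at 48 h (adjusted p = 0.0695), with arrays centred on their medians, with a stricter filter, after scaling on the control transcripts, and against all 4 arrays at 48 h. In the unscaled values the apoptosis median was -0.24 and the cytokine receptor median -0.05, both above that of all probe sets.

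The remaining lists did not pass as lists at 72 h. Among 14 IL-21 and STAT3 response genes 7 were higher and 7 lower (median 0.05), and those called were Irf4, a transcription factor gene induced by antigen receptor signalling, which fell from 1932 to 346 (-2.48, SE 0.12, limma adjusted p = 0.00678), and Cish. Socs3 differed by 1.68 (SE 0.76, adjusted p = 0.224). Of the 9 cytotoxic molecules, Serpinb9 was called lower (-1.02), while Gzmb had signals of 3630 and 3717 (0.03, SE 0.61). Neither Ctsc (-0.97, other probe sets -0.90 and 0.63) nor Prf1 (0.70, SE 0.86) passed. Among effector and memory transcription factors (median 0.02) Irf4 and Egr2 (-1.66) were called lower and Lef1 higher. In the T cell receptor and CD8 list (median 0.34, camera adjusted p = 0.0826) Cd3g (397 to 1360, 1.78), Cd3d (431 to 1135, 1.40) and, chosen after its value was seen, Thy1 (0.58) were called higher. Activation and costimulation receptors had a median of 0.01, with Klrk1, which encodes NKG2D (1.62), and, chosen after its value was seen, Il2rb (1.18) called higher and Tfrc, the transferrin receptor (-0.82), lower. Il2ra differed by -0.94 (SE 0.40, adjusted p = 0.198). Inhibitory receptors had a median of 0.63 (camera adjusted p = 0.150), with Cd160 (1.95) called higher and Cd200 (-2.72) lower. Interferon-stimulated genes had a median of 0.29 (camera adjusted p = 0.0924), with Samhd1 (1.31) called and Tap2 (0.89) not. Adjusted over the list alone, the counts called higher and lower were 0 and 2 for the IL-21 and STAT3 list, 1 and 2 for cytotoxic molecules, 1 and 2 for transcription factors, and 5 and 1 for the T cell receptor and CD8 list. They were 3 and 1 for activation receptors, 3 and 1 for inhibitory receptors, and 0 and 0 for interferon-stimulated genes. Without the first IL-21-free array the inhibitory receptors passed (adjusted p = 0.0451), and without the first IL-21 array at 48 h the interferon-stimulated genes did (adjusted p = 0.0168).

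Markers of other cell types did not pass as lists at 72 h, with camera adjusted p between 0.589 and 0.650. Of 9 measured B cell markers Cd37, which T cells also express, was called higher (1.64), and Spib differed by -1.65 without passing. Of 18 myeloid and dendritic cell markers the MHC class II gene H2-Ab1 was called higher (59.1 to 140, 1.24, SE 0.23), and Cd68 differed by 1.20 without passing. None of the 5 CD4 and regulatory T cell markers passed, including Cd4 (1.42) and Tnfrsf4 (-0.61), nor did the 6 erythroid, platelet and stromal markers, including Pecam1 (1.55) and Gata1 (-0.98). Adjusted over the list alone, 1 B cell marker and 1 myeloid marker were called higher and no others. Median, mean and camera direction differed in sign in 4 of the lists at 72 h, none of them past the threshold.

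List medians at 72 h depended on the scaling. Over the 5 scalings they lay between -2.02 and -1.11 for the MYC list, -0.96 and -0.07 for stress genes, -0.91 and -0.01 for cell cycle genes and -1.38 and -0.55 for cytokines. They lay between 0.13 and 1.05 for naive and memory genes, 0.18 and 1.04 for homing receptors, -0.10 and 0.81 for glycolysis genes, -0.05 and 0.86 for cytokine receptors, -0.27 and 0.63 for cholesterol genes and -0.24 and 0.64 for apoptosis genes, with the unscaled values lowest in each. With each 48 h array left out in turn, medians lay between -0.66 and -0.28 for stress genes, -1.47 and -0.74 for cytokines and 0.45 and 0.84 for homing receptors. Of the 22 lists, 7 had medians of either sign across these fits, none of them past the threshold, such as IL-21 and STAT3 genes (-0.21 to 0.30) and cytotoxic molecules (-0.43 to 0.39).

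The single-gene calls at 72 h rested on the shared variance trend and on both IL-21 arrays at 48 h: 0 probe sets passed without the trend (1843 at an unadjusted p under 0.05), and 0 without either of these arrays (1703 and 1748). Leaving out the first or the second IL-21-free array gave 465 and 432 calls. Of the 47 genes named above by the fixed rule that passed, all kept their sign under each of the 16 alternatives that measured them, although 0 of the 47 passed without the trend or without either IL-21 array. Both comparisons used the IL-21 arrays at 48 h with opposite sign. Across probe sets, which are not independent replicates, their log2 differences had a correlation of -0.20, where 100 simulations without any effect gave -0.41, and a covariance of -0.051 against -0.045.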

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

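The tests of this pattern were chosen only after the result was seen. The labelled control transcripts, which belong to no comparison of cells, differed between the groups: their median log2 difference between arrays with and without IL-21 at 48 h was 0.69 in the unscaled values, higher in 9 of 9 probe sets. The other probe sets had a median difference of 0.57, and 96.0% of them were higher, so the shift was not limited to a set of IL-21-responsive genes. Whether an array-wide difference in brightness of hybridisation, staining or scanning was the source was left open, since the only value on it is the same 0.69 that raised the question. The amount of control transcript added to each hybridisation is not given in the sources used here, so a difference in that amount stays open. Total RNA per cell would not by itself raise these controls, which do not come from the cells and were higher in 9 of 9 probe sets. Whether it added to the shift of the other probe sets was not tested. With both brighter arrays in 1 group, a change common to all genes could not be separated from brightness.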

How the results depend on the processing

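At 48 h the count of 0 called probe sets became 696 (696 higher, 0 lower) in the unscaled deposited values and 38 (3 higher, 35 lower) after scaling on the control transcripts, an alternative chosen after seeing the data. The median of all probe sets moved by 0.57 and -0.42 there, on the side of most of these calls. Scaling on the control transcripts used each array's median over their 9 probe sets. That is another summary than the median difference of 0.69 given above, so the shift of -0.42 and the calls under it depend on the summary chosen. The other scalings, offsets, filters and variance options and all leave-one-out fits gave 0. The count of 103 probe sets at least 2-fold apart without overlap was 536 unscaled, 222 on control transcripts, 524 without the filter and 17 with the stricter one, and 222 to 251 with an array left out, where 1 array cannot overlap itself. The 2 lists called at 48 h became 6 unscaled, 1 with arrays centred on their medians, 1 without the filter, 1 on control transcripts, 0 without the trend, 0 with an estimated correlation, 0 in fry, and 0 to 4 with an array left out. Each of the 2 calls held in 10 of 18 alternatives. In the unscaled values the glycolysis median turned to 0.42 (camera adjusted p = 0.956). The oxidative phosphorylation median, not called otherwise, went from -0.04 to 0.55 with a call upward (camera adjusted p = 0.00247). Both lay below the 0.57 of all probe sets there, and both medians were below that of all probe sets under all 5 scalings. Of 103 named values at 48 h, 31 changed sign unscaled and 19 on control transcripts.

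At 72 h the 832 calls became 2128 (101 higher, 2027 lower) unscaled, 0 without the trend and 0 to 465 with an array left out. The 0 came from leaving out either IL-21 array at 48 h, which leaves 1 array against 1 and 1 residual degree of freedom. Apart from the replicate block below, the other alternatives gave 591 to 1238, the latter (481 higher, 757 lower) against all 4 arrays at 48 h, with 788 calls among the 832, all of the same sign. Of the 10 list calls, 0 held with an estimated correlation and only that of the MYC list held in fry. Fry gave the other called lists an adjusted p between 0.0742 and 0.236, and it called the oxidative phosphorylation list, which camera had not. The other alternatives gave 8 to 11 list calls. The MYC call held in 17 of 18 alternatives, the glycolysis, naive and memory, stress and homing calls in 16, the cytokine receptor call in 15, and the cell cycle, cholesterol, cytokine and apoptosis calls in 11 to 13. Except where stated, the cause was not tested. Dim probe sets near background limit what arrays of this kind resolve.

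Replicate numbers are shared between the groups. With only 2 pairs, whose replicate differences had r = 0.361 across probe sets (rho 0.327), they were taken as numbers only. A fit with a replicate block gave 11 calls at 48 h (9 higher, including Gzmb and Cd8a, and 2 lower) and 1860 at 72 h (860 higher, 1000 lower). It ended 1 list call, that of cholesterol synthesis. Splitting the 48 h arrays by replicate number gave 46 calls (944 at an unadjusted p under 0.05), against 0 (329) by IL-21 and 0 (104) for the crossed split. At 48 h, arrays of the same number but different treatment correlated at r = 0.971 and 0.968. Those of the same treatment had 0.960 and 0.957, and those differing in both had 0.952 and 0.957. The 48 h counts thus depend on whether the numbers mark a shared source, which is not known. No label ties the numbers to a day, batch or mouse.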

Other observations

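Beyond the fixed lists, gene families defined by the stem of their symbols were compared between 72 and 48 h with IL-21, a test chosen after seeing the data. Of 74 families, 11 were called lower and 0 higher in camera with its preset correlation, and none held with an estimated correlation (lowest adjusted p = 0.708). The latter test rests on 2 residual degrees of freedom, so the lost calls do not by themselves weigh against these families. Regulatory proteasome subunits (Psmd, 13 genes) had a median log2 difference of -0.96, with 7 genes called lower (adjusted p = 1.5e-04). Nucleoporins (Nup, 8 genes, -0.80), RNA polymerase subunits (Polr, 19 genes, -0.74), translation initiation factors (Eif, 37 genes, -0.50) and splicing factors (Srsf, 9 genes, -0.62) were lower as well. So were RNA-binding motif proteins (Rbm, -0.74), mitochondrial import proteins (Timm, -0.71), mitochondrial ribosomal proteins (Mrps, -0.42, and Mrpl, -0.28), DEAD-box helicases (Ddx, -0.53) and chaperonins (Cct, -0.54). Genes called lower were 5 of 8 for Nup, 5 of 19 for Polr, 6 of 37 for Eif, 4 of 9 for Srsf and 2 of 11 for Rbm. They were 4 of 11 for Timm, 4 of 21 for Mrps, 8 of 38 for Mrpl, 7 of 22 for Ddx and 1 of 8 for Cct. The medians of all 11 families were below 0 under all 5 scalings. The MYC list holds 4 of the Polr genes, 2 each of Eif, Ddx and Cct, and none of the others. Cytosolic ribosomal protein genes had medians of 0.03 (Rpl, 11 genes) and 0.07 (Rps, 15 genes), and neither family was called, with 1 Rpl gene called higher. Another proteasome family, Psmb (10 genes), had a median of -0.09 with 1 gene called lower, and was not called (camera adjusted p = 0.893). Only families of at least 8 measured genes were tested, so not every proteasome subunit is covered. At 48 h, IL-21 against none gave 0 of 74 families, with a lowest adjusted p of 0.815.

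The tests below were written before their results were seen, except the 3' to 5' ratios for the MYC list and the estimated correlation for the 48 h lists.

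The MYC and ribosome biogenesis list was lower at 72 h, with a median of -1.27. Degraded RNA on the 72 h array predicts 3' to 5' ratios above those at 48 h, but the ratio for beta-actin was 0.886 against at most 1.03, and neither Gapdh nor the transferrin receptor exceeded its highest 48 h value. A shift of all probe sets of similar signal is argued against because 95% of matched random lists had medians between -0.31 and 0.16. Spread between arrays is argued against because the nearest 48 h array still differed by -1.23, while the largest difference among 48 h arrays was 0.09 in size. With 1 array at 72 h, a property of that single culture or array cannot be told apart from time in culture, which stays an untested hypothesis.

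The cell cycle list was higher and the glycolysis list lower with IL-21 at 48 h. A shift of probe sets of similar signal is argued against, since their medians lay at the 99.9th and 0.300th percentile of matched random lists. Whether correlation between the genes of a list accounts for both calls was not decided. With an estimated correlation the adjusted p in camera was 0.894 for each. That test rests on 2 residual degrees of freedom, and no list of either comparison passed it. It also ended the 72 h cholesterol and apoptosis calls, whose estimated correlations, 0.0013 and 0.0092, lay below the preset 0.01. A call lost in it is thus by itself no sign of correlated genes, a weighing settled after the value was seen. That 1 array carries both calls would need a single removal to end both, but 3 of the 4 did, and all 4 differences between an IL-21 array and an IL-21-free array kept the sign (0.04 to 0.13 for cell cycle, -0.27 to -0.08 for glycolysis). The smallest of these are no larger in size than the differences between the 2 IL-21-free arrays (-0.04 and 0.10), so the explanation stays open. An effect of IL-21 on both lists remains a hypothesis that these 4 arrays do not settle.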
